A study of Mus musculus with 22 samples.

How the data were processed

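The deposited table holds 54532 genes in 22 libraries, 1 column per library, and every column matched 1 sample by its library name. Its values are whole-number counts of reads per gene, per the labels, which state that reads were aligned to GRCm38 (mm10) and counted per gene. That build is also named in the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here, so antisense, overlapping and near-identical genes (haemoglobin chains, class I and class II MHC genes, ribosomal protein genes with processed pseudogenes) have uncertain shares of their reads. Per the labels' protocols, the microglia were sorted by flow cytometry as live CD45mid, CD11b+ and CD11a- cells, RNA with an integrity number of at least 8.5 was used, and stranded poly(A) libraries were sequenced as 150 bp read pairs.

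Symbols that a spreadsheet had turned into dates were restored from the gene identifiers (27 genes), and 103 repeated symbols were set apart by identifier. Of all identifiers 54409 were found in the GENCODE M21 annotation of GRCm38, from which coordinates and gene types were taken. Library totals ran from 28676930 to 40458326 counts, 31987884 to 37407567 in Ctrl-PBS, 32491861 to 38831070 in Ctrl-LPS, 33596443 to 37517783 in GW-PBS, 32803017 to 37990923 in GW-LPS, 33100476 to 40458326 in GW-CBD-PBS, 28676930 to 37752035 in GW-CBD-LPS. Between 13906 and 15405 genes had at least 10 counts in a library. Libraries of a group were compared pair by pair with a chi-square of their counts, which ran from 11.7 to 234 per degree of freedom, so none was a repeat of another. Groups were taken from the sample labels, and libraries carry the number of their library name.

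Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM factors, genes kept by filterByExpr with the groups). All 22 libraries entered 1 fit with a mean for each of 6 groups, so the 9 contrasts share 1 estimate of the spread (common biological coefficient of variation 0.35). The test was two-sided without a fold threshold, with a Benjamini-Hochberg adjusted p under 0.05. The filter kept 16554 genes, which held 99.9% of the counts in the lowest library. CPM values of single genes use the TMM factors, and log2 CPM a prior count of 2. Summed CPM of lists and markers, and the CPM of single neutrophil markers, use library totals without these factors. An adjusted p in the text without another tool named beside it comes from this edgeR test. Design, tests, gene lists and most alternatives were fixed before the data were examined.

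Gene lists for microglial states, pathways and markers of other cell types were tested with camera of limma 3.58.1 on voom values with a preset correlation, adjusted over 297 tests of a list in a contrast, and again with an estimated correlation. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. A score of the LPS response was the mean log2 CPM of genes called higher minus that of genes called lower, with genes taken from libraries outside the comparison, and its differences were tested with exact permutation tests (two-sided). The exposure and CBD contrasts share the GW libraries with opposite sign, so their correlation was set beside simulated unchanged groups. Figures were drawn with matplotlib 3.10.9.

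Genes were named by a rule fixed before the data were examined. For each contrast these were, among called genes with a mean of at least 5 CPM in the higher group and not a predicted gene or pseudogene, the 8 with the highest and the 8 with the lowest log2 fold change. For each pathway list with at least 3 called members or a camera adjusted p under 0.05, its 3 called members with the smallest p were taken. To these were added the index genes P2ry12, Tmem119, Cx3cr1, Apoe, Trem2, Il1b, Tnf, Cxcl10, Ifit3, H2-Aa, Cd74 and Cdkn1a. Where fewer than 5 genes were called, the 5 with the smallest p were named. Not every gene of the rule is printed, some are not reported here, and genes outside it are named as chosen after their values were seen.

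Alternatives were size factors of the DESeq2 type (RLE), no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were fits without the 3 libraries with raised neutrophil markers and with the neutrophil marker sum or the ribosomal protein sum as a covariate. Each test was tried on simulated counts with 200 changed genes. For LPS in control mice (16133 genes) edgeR recovered 68.7% of 2-fold and 13.4% of 1.5-fold changes, for CBD with LPS (16154 genes) 52.2% and 19.4%, and for the interaction of CBD and LPS 20.9% of 2-fold and 0% of 1.5-fold changes. In the simulation of LPS in CBD-treated GW mice 17.5% of DESeq2 calls were of unchanged genes, against 3.7% with edgeR and 1% with limma voom. Simulated counts were drawn independently for each gene, with the same spread in all libraries. They held no library of unequal quality and no genes that vary together, so these rates need not hold for the real libraries.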

Results

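Microglia, the resident macrophages of the brain, were sorted from aged male C57BL/6J mice, and their polyadenylated RNA was sequenced. The mice modelled Gulf War Illness, a chronic condition of veterans. At 10 weeks of age they were injected for 10 days with pyridostigmine bromide (0.7 mg/kg), an acetylcholinesterase inhibitor, and permethrin (200 mg/kg), a pyrethroid insecticide, or with vehicle. They were then kept to an age of 17.5 months. Some of the exposed (GW) mice received cannabidiol (CBD), a plant cannabinoid, at 30 mg/kg daily for 28 days and every 2 days for 2 more weeks. A single injection of lipopolysaccharide (LPS, 0.33 mg/kg), a bacterial outer membrane component that activates innate immune cells, or of saline buffer (PBS) preceded brain collection by 24 hours. The 22 libraries fell into 6 groups. These were control mice given PBS (Ctrl-PBS, n = 4) or LPS (Ctrl-LPS, n = 4), GW mice given PBS (GW-PBS, n = 4) or LPS (GW-LPS, n = 3), and CBD-treated GW mice given PBS (GW-CBD-PBS, n = 3) or LPS (GW-CBD-LPS, n = 4). No library of control mice given CBD was analysed here, so CBD was compared within GW mice. Library totals ran from 28676930 to 40458326 counts, and 16554 genes were tested. The labels do not say whether each library came from 1 mouse, so p-values measure the spread between libraries.

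The 24 genes of the homeostatic microglia list summed to 69400 ± 6960 CPM (library-scaled counts, SD, n = 4) in Ctrl-PBS and to 43100 ± 5890 CPM (n = 4) in Ctrl-LPS. Markers of other brain cells stayed far lower, at 282 CPM for astrocytes and 470 CPM for oligodendrocytes in Ctrl-PBS. Neutrophil markers stood apart in single libraries. They summed to 25900 CPM in Ctrl-PBS replicate 3, 2650 CPM in Ctrl-LPS replicate 1 and 1957 CPM in GW-PBS replicate 1, against 429 to 1093 CPM in the other 19 libraries. Erythroid markers, the haemoglobin chains and heme synthesis genes, summed to 687 CPM in Ctrl-PBS and 872 CPM in GW-PBS against 102 CPM in GW-LPS.

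**Figure D1:**
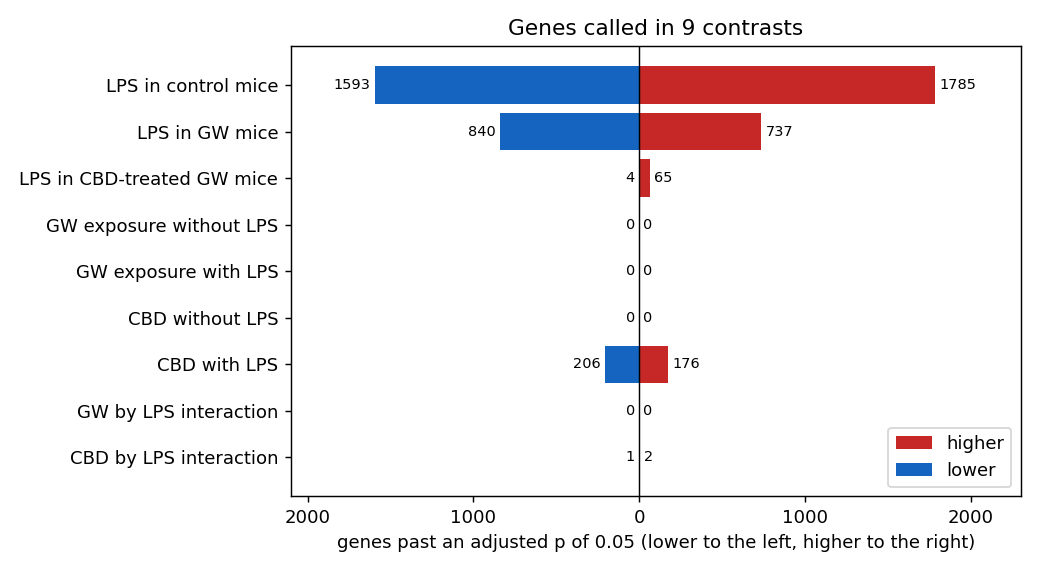
Number of genes past an adjusted p of 0.05 in the edgeR quasi-likelihood test (horizontal axis, genes lower to the left in blue and higher to the right in red) for each of 9 contrasts (vertical axis). The LPS contrasts hold 3378 genes in control mice, 1577 in GW mice and 69 in CBD-treated GW mice.

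The first comparison asked how microglia of aged control mice respond to LPS. Of the 24 homeostatic genes tested 14 fell and 1 rose, and of 36 interferon response genes 25 rose, while with an estimated correlation neither list passed (adjusted p = 0.546 and 0.584). P2ry12, a purinergic receptor that marks resting microglia (ENSMUSG00000036353, GRCm38 chromosome 3, 59216272 to 59262871), fell from 5880 ± 969 to 1350 ± 288 CPM (SD, n = 4 each), a log2 fold change of -2.12 ± 0.20 (SE). Gpr34, a lysophospholipid receptor, fell by 2.51 ± 0.22 on the log2 scale, and the lectin Siglech fell from 2310 ± 215 to 970 ± 126 CPM. The fractalkine receptor Cx3cr1 fell by 0.76 ± 0.14, and the microglial membrane protein Tmem119 fell by 0.36 ± 0.11, a call lost without any one of 4 libraries (replicate 1 or 4 of either group).

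No type I interferon response gene fell, and 28 rose adjusted over the list alone. Ifi204, an interferon-inducible DNA sensor, rose from 24.6 ± 3.5 to 144 ± 40.2 CPM (log2 fold change 2.55 ± 0.23), Slfn2 by 2.12 ± 0.24 and Zbp1, a sensor of nucleic acids that triggers necroptosis, by 3.04 ± 0.38. Among 37 cytokine and NF-kB genes 15 rose and 1, the NF-kB subunit gene Nfkb1 (-0.76 ± 0.11), fell. Bcl3, a nuclear IkB family regulator, rose by 2.93 ± 0.27 and Tnf by 1.65 ± 0.40, while Il1b differed by 1.04 ± 0.56 and did not pass (edgeR adjusted p = 0.207). Socs3, an inhibitor of cytokine signalling, rose from 224 ± 42.7 to 1480 ± 270 CPM (2.72 ± 0.29), and Nfkbia, the NF-kB inhibitor, rose by 1.56 ± 0.31.

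Phagocytic and complement genes changed in both directions. Of 38 lysosome and phagocytosis genes 15 rose and 7 fell, with the Fc receptor gene Fcgr4 (3.44 ± 0.29) and the scavenger receptor gene Msr1 (3.89 ± 0.40) among the rises. Of 14 complement genes 7 rose and 1 fell. C5ar1, the receptor of the anaphylatoxin C5a, rose from 378 ± 62.1 to 2070 ± 481 CPM (2.45 ± 0.23) and C1qb by 0.99 ± 0.17. The class II genes of antigen presentation fell, with H2-Aa at -2.80 ± 0.42, H2-Ab1 at -2.57 ± 0.39 and the invariant chain gene Cd74 at -1.62 ± 0.35. Across the 23 genes of that list 4 rose and 6 fell, its median was 0.17 and its mean -0.30, of opposite signs. The disease-associated microglia list was likewise mixed, with 8 of 26 genes higher and 7 lower. Its lysosomal members Ctsl (1.34 ± 0.15) and Cd63 (1.72 ± 0.22) and the lipid carrier gene Apoe (1.08 ± 0.26) rose, and Cd9 (-1.44 ± 0.24) and the lipid receptor gene Trem2 (-0.82 ± 0.19) fell. Fth1, the ferritin heavy chain gene, rose by 1.62 ± 0.25, Hmox1, which degrades heme, by 1.38 ± 0.19 and the lipid droplet gene Plin2 by 1.98 ± 0.26, while Mgll, which hydrolyses an endocannabinoid, fell by 1.37 ± 0.22.

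The largest rises were in genes that were almost silent without LPS. Saa3, an acute phase serum amyloid gene, went from 0.101 ± 0.202 to 237 ± 181 CPM, Plet1 from 0.195 ± 0.135 to 78.2 ± 58.3 CPM, and Adamtsl4, a secreted matrix protein gene, from 1.34 ± 0.563 to 104 ± 43.8 CPM (6.28 ± 0.57). Cd244a, a receptor of the SLAM family, rose from 3.72 ± 1.3 to 210 ± 25.8 CPM (5.82 ± 0.44), the B cell chemokine gene Cxcl13 by 5.11 ± 0.74 and the decoy receptor gene Il1r2 by 4.56 ± 1.29, a call lost without Ctrl-LPS replicate 1. Cytosolic ribosomal protein genes rose in 46 of 80 cases, or in 11 without Ctrl-LPS replicate 1, with Rpl4 at 0.93 ± 0.18. Of 54 oxidative phosphorylation genes 9 rose, Atp5b among them (0.63 ± 0.11), a count that ran from 4 (without Ctrl-PBS replicate 3) to 18 when 1 library was left out. Of 36 cell cycle genes 11 fell, such as Ccnb1 (-2.63 ± 0.69) and Cenpf (-1.42 ± 0.32), and 3 were left without the 3 libraries with raised neutrophil markers. Among the largest falls were the granulocyte genes Fcnb, Elane, Camp and Cebpe. Fcnb, at 38.3 ± 76.5 CPM in Ctrl-PBS, had no value without Ctrl-PBS replicate 3, where it did not reach the count filter. The calls of Ccnb1, Elane, Camp and Cebpe were lost without Ctrl-PBS replicate 3, that of Camp also without Ctrl-LPS replicate 2, 3 or 4 and that of Elane also without Ctrl-LPS replicate 4. Elane fell by 9.54 ± 2.70 with all libraries but had a log2 fold change of 5.45 without Ctrl-PBS replicate 3.

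In total 3378 genes passed in control mice, 1785 higher and 1593 lower (edgeR, adjusted p under 0.05), and 2316 without the 3 libraries. Without them 13 homeostatic genes fell and 1 rose, 20 interferon and 19 ribosomal protein genes rose, and 10 cytokine genes rose and 2 fell. Without Ctrl-LPS replicate 1 alone 9 cytokine, 5 disease-associated and 0 MHC genes rose and 4 lysosome genes fell in edgeR, and without Ctrl-PBS replicate 3 alone 2 cell cycle genes fell. With the ribosomal protein sum as a covariate, chosen after seeing the data, 26 oxidative phosphorylation genes fell and 3 rose. In the gene list test the homeostatic, interferon, cytokine, ribosomal protein, oxidative phosphorylation and complement lists passed with the preset correlation. With an estimated correlation their adjusted p values were 0.546, 0.584, 0.744, 0.744, 0.809 and 0.546, so none passed.

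The same question in GW mice gave falls in 13 of 24 homeostatic genes, or 8 without GW-PBS replicate 1. P2ry12 fell from 5120 ± 811 (SD, n = 4) to 1620 ± 202 CPM (n = 3), a log2 fold change of -1.66 ± 0.21 (SE), Gpr34 fell by 1.95 ± 0.24 and Siglech fell by 1.08 ± 0.16. Of 26 disease-associated genes 10 fell and 1 rose, including Cd9 (-1.97 ± 0.27), the pattern receptor gene Clec7a (-1.96 ± 0.29) and Trem2 (-1.32 ± 0.21), and of 23 MHC genes 11 fell, led by H2-Aa (-2.87 ± 0.47), H2-Ab1 (-2.68 ± 0.44) and Cd74 (-2.15 ± 0.40). Interferon genes passed in 5 of 36 cases, all higher (2 without GW-PBS replicate 1), with Slfn2 at 1.28 ± 0.25, Ifi204 at 1.05 ± 0.23 and Irf9 at 0.43 ± 0.12. The call of Irf9 was lost without GW-PBS replicate 1 or any 1 of the 3 GW-LPS libraries.

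In GW mice C5ar1 rose from 406 ± 19 to 1600 ± 728 CPM (1.98 ± 0.23), Fcgr4 by 2.50 ± 0.29, Msr1 by 3.02 ± 0.40 and Cd244a by 4.70 ± 0.42, and Adamtsl4 rose from 1.47 ± 0.278 to 71.2 ± 62.3 CPM (5.60 ± 0.56). Il1r2 rose by 6.13 ± 1.45, a call lost without GW-LPS replicate 3, and Plet1 by 5.18 ± 0.96. The complement gene C4b rose by 2.34 ± 0.48, while the integrin gene Itgax (-2.04 ± 0.34), the lipase gene Lpl (-2.31 ± 0.38) and the metalloelastase gene Mmp12 (-4.26 ± 0.55) fell. Of 37 cytokine and NF-kB genes 2 rose, Bcl3 (2.16 ± 0.27) among them, and 3 fell, including Nfkb1 (-0.67 ± 0.12) and Relb (-0.97 ± 0.25), the latter lost without GW-LPS replicate 3 or 4. Leaving out 1 library gave 1 (without GW-PBS replicate 1) to 3 rises and 1 (without GW-LPS replicate 3) to 4 falls. Tnf (0.33 ± 0.42) and Apoe (-0.70 ± 0.28) did not pass. Socs3 rose by 2.02 ± 0.30, and the inhibitory receptor genes Cd200r1 (-0.92 ± 0.15) and Pdcd1 (-1.32 ± 0.29) fell. No ribosomal protein gene passed. Of 8 erythroid markers 6 fell, or 1 without GW-LPS replicate 2, Hbb-bt by 3.89 ± 0.83. In control mice 5 had fallen, or 1 without Ctrl-PBS replicate 2, Hbb-bt by 2.28 ± 0.69, a call lost there without Ctrl-PBS replicate 2 or Ctrl-LPS replicate 2 or 4. Hbb-bt was chosen after its values were seen.

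In GW mice 1577 genes passed, 737 higher and 840 lower (edgeR), and 1120 without the 3 libraries with raised neutrophil markers. The count was 956 without GW-PBS replicate 1, 889 without GW-LPS replicate 3, 733 without GW-LPS replicate 4 and 607 when only these 7 libraries were fitted. The homeostatic, disease-associated and MHC lists passed with the preset correlation, and their adjusted p values with an estimated correlation were 0.546, 0.637 and 0.56.

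Whether LPS acted differently in GW and control mice was tested as the interaction of both factors. The responses shared 527 rises and 535 falls, against 79.5 and 80.8 for independent lists, and 2 genes were called in opposite directions. Across genes the GW response followed the control response with a slope of 0.49 (Pearson r = 0.579 over 16554 genes, which are not independent replicates). Library noise in the control fold changes pulls this slope towards 0, so it does not measure the relative size of the GW response. All 36 interferon genes had a negative interaction, 22 of them past the threshold adjusted over the list alone, with a median of -1.16. Rtp4, an interferon-induced chaperone gene, had -1.93 ± 0.41, and the microglial genes Apoe (-1.78 ± 0.39), Cst7 (-2.17 ± 0.48) and Spp1 (-2.58 ± 0.63) were of the same sign. Saa3 (-7.96 ± 1.67), Cxcl13 (-4.98 ± 1.00) and Ly6i (-3.72 ± 0.71) were among the smallest p. Ribosomal protein genes were negative in 79 of 80 cases (median -0.93), with 0 past the threshold adjusted over the list alone. Rtp4, Cst7 and Spp1 were chosen after their values were seen.

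No gene passed this interaction over all genes tested in edgeR (smallest adjusted p = 0.211), with 2099 genes at an unadjusted p under 0.05 where 828 were expected by chance. That number was 1219 without GW-PBS replicate 1, 1383 without Ctrl-LPS replicate 1, 3446 without GW-PBS replicate 2 and 854 without the 3 libraries with raised neutrophil markers. DESeq2 called 57 and limma voom with quality weights 111, and edgeR called 13 without Ctrl-LPS replicate 3. With an estimated correlation the adjusted p values of the interferon and ribosomal protein lists were 0.584 and 0.738. A score planned before the data were examined, built on the 56 genes called higher and 3 called lower for LPS in CBD-treated mice alone, differed between LPS and PBS by 4.43 in control mice (exact permutation p = 0.114) and by 3.24 in GW mice (exact p = 0.257). The difference of -1.2 had an exact permutation p of 0.706 (two-sided, all relabellings). It was positive without Ctrl-PBS replicate 3 (0.20), GW-PBS replicate 4 (0.53) or GW-LPS replicate 3 (0.10). In this score the 3 lower genes weigh as much as the 56 higher ones, and its lowest value was -6.154 in Ctrl-PBS replicate 3. As it did not separate LPS from PBS libraries even in control mice, it cannot decide whether the responses differ. Over the fixed interferon and cytokine lists the difference was -1.05 (exact permutation p = 0.0229). It was taken in the libraries and genes in which the lower interferon list had been seen. It therefore restates that pattern and does not decide the question either.

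In CBD-treated GW mice 5 of 36 cell cycle genes rose with LPS, and that list had an adjusted p of 0.56 with an estimated correlation. Mcm7, a subunit of the replicative helicase, went from 25.2 ± 1.03 (SD, n = 3) to 102 ± 42.5 CPM (n = 4), a log2 fold change of 2.02 ± 0.36 (SE). The sliding clamp gene Pcna rose by 1.3 ± 0.25, the cyclin gene Ccne1 by 3.79 ± 0.81, the thymidine kinase gene Tk1 by 2.76 ± 0.59 and the chromatin assembly gene Chaf1b by 2.79 ± 0.47. Adjusted over the list alone 18 cell cycle genes rose, and 35 were higher. In GW mice without CBD, Mcm2 also rose with LPS, from 18.6 ± 10.7 to 68.5 ± 50.8 CPM, and Mcm6 from 30.8 ± 8.14 to 81.9 ± 45.8 CPM. Both calls were lost in 5 of the 7 fits that left out 1 library, which gave 0 to 4 cell cycle rises there. GW-CBD-LPS replicate 3 lay apart, with a cell cycle sum of 584.4 CPM against 1328 to 1695 CPM in the other 3 libraries.

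Interferon genes were higher in 35 of 36 cases, 2 past the threshold over all genes and 23 adjusted over the list alone. Ifi204 rose by 1.14 ± 0.24 and Ifi27l2a from 18.1 ± 2.57 to 67 ± 20.1 CPM (1.89 ± 0.39), and Ifit3 had 0.88 ± 0.33 (edgeR adjusted p = 0.307). Cd244a (2.67 ± 0.42) and Tcf19 (2.89 ± 0.45) also rose. Oxidative phosphorylation genes were higher in 54 of 54 cases, 0 past the threshold over all genes in edgeR and 30 adjusted over the list alone (adjusted p = 0.613 with an estimated correlation), and ribosomal protein genes in 78 of 80, 18 adjusted over the list alone (adjusted p = 0.738 with an estimated correlation). GW-CBD-LPS replicate 4 stood apart for both lists. Its sums were 8865 and 10640 CPM against 6165 to 6955 and 5789 to 6720 CPM in the rest of its group. No homeostatic gene passed in edgeR. P2ry12 was at 5340 ± 376 without and 3600 ± 1090 CPM with LPS (-0.57 ± 0.20, adjusted p = 0.275), and H2-Aa differed by -1.41 ± 0.42 (adjusted p = 0.181). In GW-CBD-LPS replicate 3 P2ry12 was at 5077.07 CPM, within the 4907.39 to 5593.79 CPM of the GW-CBD-PBS libraries. The 4 genes that fell were Phf1 (-0.88 ± 0.19), Rnase10 (-1.52 ± 0.32) and the predicted genes Gm3173 and Gm3005.

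With 69 genes past the threshold, 65 higher and 4 lower, this contrast rested on few calls. It kept 0 without any one of the 3 GW-CBD-PBS libraries, 4 without GW-CBD-LPS replicate 1 or 4, 10 without replicate 2, 260 without replicate 3 and 155 without the 3 libraries with raised neutrophil markers. The calls of Cd244a and Tcf19 were lost without any 1 of the GW-CBD-PBS libraries, those of Pcna and Chaf1b in 5 of the 7 fits that left out 1 library, and those of Mcm7, Tk1, Ccne1, Ifi204, Ifi27l2a, Phf1 and Rnase10 in 6 of the 7. DESeq2 called 342 and limma voom with quality weights 2071 higher and 1708 lower. The voom weights were 5.94 for GW-CBD-LPS replicate 1 and 4.05 for GW-CBD-PBS replicate 4, against 0.43 to 1.36 for the rest of these libraries. Its counts therefore lean on single libraries. The interferon list had an adjusted p of 0.56 with an estimated correlation.

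**Figure D2:**
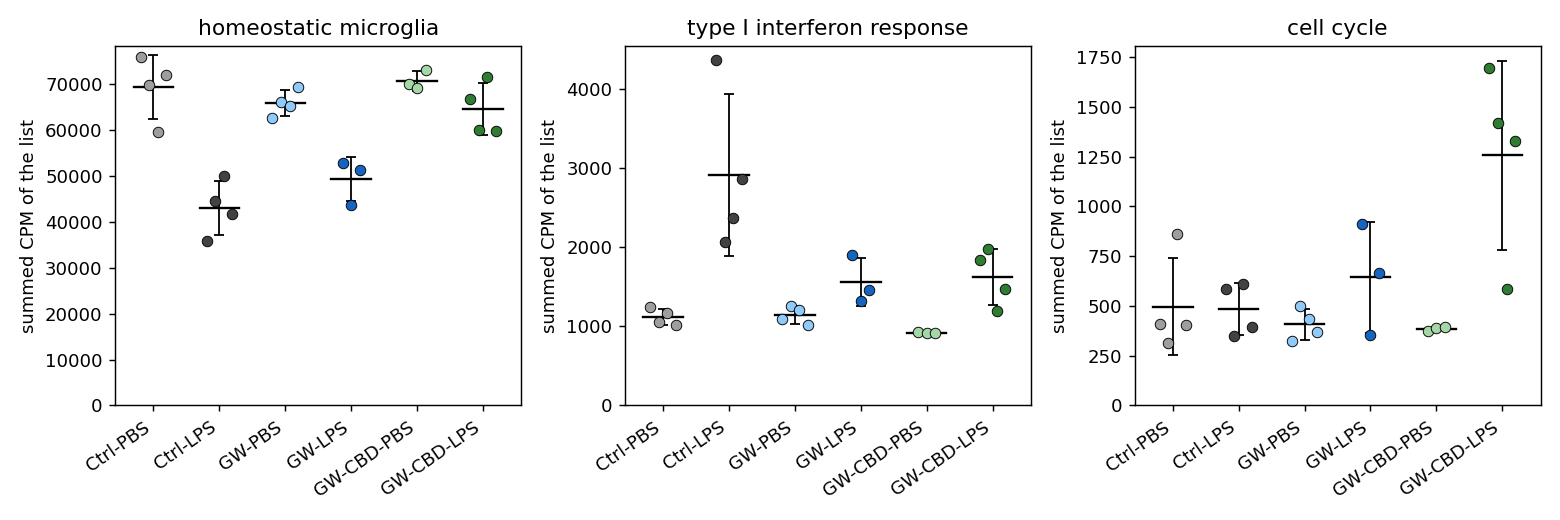
Summed CPM (vertical axes, from 0) of the homeostatic microglia, type I interferon response and cell cycle lists in each library (points), with the group mean (line) and SD (bars) of 6 groups. The homeostatic sum averaged 43100 CPM in Ctrl-LPS and 64600 CPM in GW-CBD-LPS, and 1 of 4 GW-CBD-LPS libraries lay at 584.4 CPM in the cell cycle panel.

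The effect of early chemical exposure on its own was read from GW-PBS against Ctrl-PBS. Genes of disease-associated microglia were higher in GW mice in 25 of 26 cases, with 11 past the threshold adjusted over the list alone and none over all genes tested. The sum of the list was 51870 and 42110 CPM in GW-PBS replicates 3 and 1. It was 35090 and 33830 CPM in replicates 2 and 4, close to or within the 29960 to 34910 CPM of the Ctrl-PBS libraries. Cst7, a cystatin of activated microglia, was at 118 ± 59.4 against 54.4 ± 7.48 CPM (SD, n = 4 each; log2 fold change 1.11 ± 0.32 SE), Fabp5, a fatty acid binding protein gene, differed by 1.18 ± 0.35, Lpl by 1.02 ± 0.33, Spp1 (osteopontin) by 1.21 ± 0.42 and Apoe by 0.75 ± 0.26. All but Apoe were chosen after their values were seen, and for all but Apoe the libraries of both groups overlapped. Neutrophil and monocyte markers were lower in GW-PBS in 12 of 12 and 10 of 11 cases, which goes with the single Ctrl-PBS library described above.

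edgeR called 0 genes, the smallest adjusted p was 1, and 621 genes had an unadjusted p under 0.05 against 828 expected by chance, or 1068 without GW-PBS replicate 2 and 495 without the 3 libraries with raised neutrophil markers. DESeq2 and limma voom also called 0. The smallest p belonged to Ndrg1 (-1.36 ± 0.31), Saa3 (5.30 ± 1.33), Prg4 (-6.33 ± 1.63) and Rsph3a (0.70 ± 0.18). Simulated changes of 2-fold were recovered in 71.6% of cases in this contrast, and those of 1.5-fold in 16.4%. The disease-associated list passed with the preset correlation and had an adjusted p of 0.546 with an estimated correlation.

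After LPS, exposed and control mice were compared as GW-LPS against Ctrl-LPS. Every interferon response gene was lower in GW mice, 36 of 36, and 23 passed adjusted over the list alone. Rtp4 was at 48.4 ± 16.2 (SD, n = 3) against 161 ± 76 CPM (n = 4), a log2 fold change of -1.73 ± 0.31 (SE), and Oasl2, an antiviral gene, had -1.78 ± 0.34. Usp18 (-1.60 ± 0.33), Xaf1 (-1.3 ± 0.27), Ifit3 (-1.35 ± 0.33) and the chemokine gene Cxcl10 (-1.51 ± 0.56) had the same sign. Of 23 MHC genes 17 were lower, 13 past the list-alone threshold, among them the class I genes H2-T23 (-0.80 ± 0.17), H2-K1 (-0.93 ± 0.23) and H2-D1 (-0.77 ± 0.19). Ribosomal protein genes were lower in 79 of 80 cases (median -0.56), and Apoe differed by -1.03 ± 0.29. Oasl2, Usp18, Xaf1 and the class I genes were chosen after their values were seen.

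Over all genes edgeR called 0 genes (smallest adjusted p = 0.106), with 2267 at an unadjusted p under 0.05 against 828 by chance, while DESeq2 called 135 and limma voom with quality weights 324. The 2267 became 1078 without Ctrl-LPS replicate 1, 1423 without Ctrl-LPS replicate 4 and 1354 without the 3 libraries. Without Ctrl-LPS replicate 2 edgeR called 30 and without replicate 3 it called 75, and the interferon and MHC lists had adjusted p values of 0.56 and 0.594 with an estimated correlation. Ctrl-LPS replicate 1, with raised neutrophil and monocyte markers, had the highest interferon sum, and without the 3 libraries the list median moved from -0.94 to -0.68.

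CBD without LPS was read from GW-CBD-PBS against GW-PBS. Of 80 cytosolic ribosomal protein genes 78 were lower with CBD and 57 passed adjusted over the list alone, while 0 passed over all genes in edgeR and the list had an adjusted p of 0.641 with an estimated correlation. The highest of these 7 ribosomal sums, 10900 CPM, was that of GW-PBS replicate 1. Erythroid markers were at 277 CPM with CBD and 872 CPM without. The latter mean came from 1576 and 1374 CPM in GW-PBS replicates 1 and 3. Replicates 2 and 4, at 275.9 and 260.3 CPM, lay within the 216.4 to 383.7 CPM of the GW-CBD-PBS libraries. Choroid and ependymal markers were at 52.6 CPM with CBD and 262 CPM without, the latter with 752 CPM in GW-PBS replicate 4 against 65.9 to 132 in the other 3 libraries. Rps27 was at 24.7 ± 4.45 (SD, n = 3) against 57.7 ± 30.3 CPM (n = 4; log2 fold change -1.23 ± 0.32 SE). Oxidative phosphorylation genes were lower in 51 of 54 cases, 32 of them past the list-alone threshold, as for the cytochrome oxidase gene Cox8a (-0.94 ± 0.31). Of 26 disease-associated genes 25 were lower and 6 passed list-alone, including Cst7 (-1.31 ± 0.36) and Fabp5 (-1.41 ± 0.39), and Apoe differed by -0.54 ± 0.28. The sum of that list was 27870 to 37120 CPM in the GW-CBD-PBS libraries, a range that holds GW-PBS replicates 2 and 4 (35090 and 33830 CPM). Rps27, Cox8a, Cst7 and Fabp5 were chosen after their values were seen.

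edgeR called 0 genes (smallest adjusted p = 0.524), with 1569 at an unadjusted p under 0.05, of which 1172 were lower, and 828 by chance. The 1569 became 523 without GW-PBS replicate 1, 649 and 830 without GW-CBD-PBS replicate 2 or 4, 600 without the 3 libraries with raised neutrophil markers and 3303 without GW-PBS replicate 2. DESeq2 called 0 and limma voom with quality weights 217, and Tada2b (2.07 ± 0.47) and the checkpoint gene Hus1 (0.58 ± 0.14) had the smallest p. The ribosomal list median moved from -0.80 to -0.45 without the 3 libraries with raised neutrophil markers. With an estimated correlation the adjusted p was 0.712 for the oxidative phosphorylation and 0.59 for the disease-associated list.

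The effect of CBD after LPS was read from GW-CBD-LPS against GW-LPS. Of 24 homeostatic genes 5 rose, or 2 without GW-LPS replicate 3, with an adjusted p of 0.546 for the list with an estimated correlation. P2ry12 was at 3600 ± 1090 (SD, n = 4) against 1620 ± 202 CPM (n = 3), a log2 fold change of 1.15 ± 0.21 (SE), Gpr34 rose by 1.39 ± 0.23 and Siglech by 0.90 ± 0.16. Adjusted over the list alone 14 homeostatic genes rose. C5ar1 was at 453 ± 112 against 1600 ± 728 CPM (-1.82 ± 0.23), and Msr1 (-2.27 ± 0.39), Fcgr4 (-1.43 ± 0.28) and the inhibitory Fc receptor gene Fcgr2b (-0.63 ± 0.13) fell.

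Adamtsl4, at 3.66 ± 2.03 CPM with CBD and 71.2 ± 62.3 CPM without, fell (log2 fold change -4.28 ± 0.53), as did Plet1 (-6.74 ± 1.07), Il1r2 (-7.94 ± 1.62), the kinase gene Map3k6 (-4.59 ± 0.75) and the receptor gene Cd300lf (-4.41 ± 0.85). Cell cycle genes were higher in 36 of 36 cases, 4 past the threshold over all genes (0 without GW-LPS replicate 3 in edgeR) and 20 adjusted over the list alone, with Ccne2 at 3.10 ± 0.64, Tk1 at 2.99 ± 0.59, Stmn1 at 1.86 ± 0.37 and Cdk1 at 2.04 ± 0.52. Npnt, an integrin ligand gene, rose by 2.40 ± 0.45 and Duoxa1 by 3.81 ± 0.71. Pdcd1, an inhibitory receptor gene, rose by 1.29 ± 0.29 and the transcription factor gene Batf fell by 0.77 ± 0.18. Trem2 (0.74 ± 0.20, adjusted p = 0.0597) and Ifit3 (1.09 ± 0.33, adjusted p = 0.0906) did not pass in edgeR.

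In all 382 genes passed, 176 higher and 206 lower. Of the genes that fell 189 had risen with LPS in control mice (22.2 for independent lists), and of those that rose 146 had fallen there (16.9 for independent lists), in libraries the contrasts do not share. When only the 7 libraries of these 2 groups were fitted, edgeR called 0 genes, with 2047 at an unadjusted p under 0.05. In the fit of all libraries the count was 97 without GW-LPS replicate 3, 152 without GW-LPS replicate 4, 158 without GW-CBD-LPS replicate 1 and 190 without GW-CBD-LPS replicate 3. Without GW-LPS replicate 3 the calls of P2ry12, Il1r2, Cd300lf, Ccne2, Tk1, Stmn1, Npnt, Duoxa1 and Fcgr2b were lost. Il1r2 was also lost without GW-CBD-LPS replicate 1, Ccne2 without GW-LPS replicate 4 and Fcgr2b without either, and Pdcd1 and Batf without GW-LPS replicate 3 or 4 or GW-CBD-LPS replicate 1 or 3. Cdk1 was lost in 6 of the 7 fits that left out 1 library, and Gpr34, Siglech, C5ar1, Msr1, Fcgr4, Adamtsl4, Plet1 and Map3k6 were kept in all 7. Without the 3 libraries with raised neutrophil markers 672 genes passed. C5ar1 and Cdk1 were chosen after their values were seen. The cell cycle list had an adjusted p of 0.584 with an estimated correlation.

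**Figure D3:**
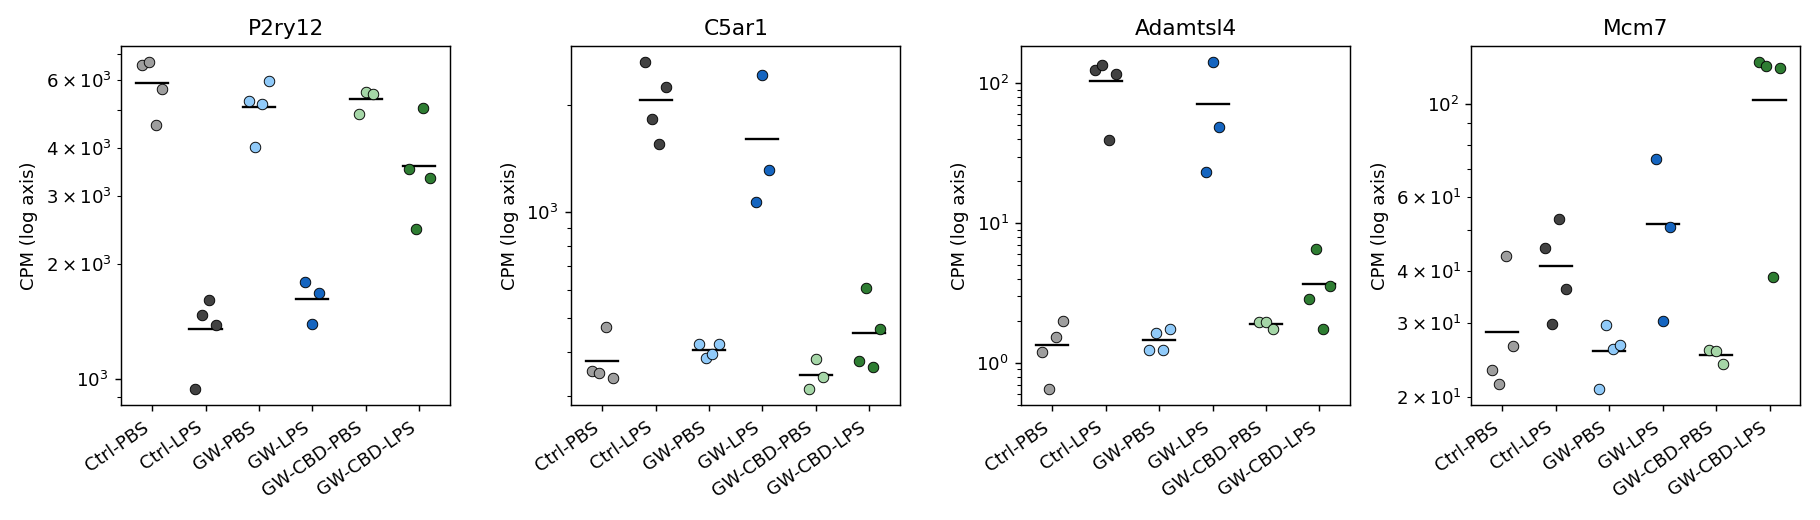
CPM on log axes (vertical) of P2ry12, C5ar1, Adamtsl4 and Mcm7 in each library (points) of 6 groups, with the group mean as a line. P2ry12 averaged 1350 CPM in Ctrl-LPS, 1620 CPM in GW-LPS and 3600 CPM in GW-CBD-LPS.

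Whether CBD changed the LPS response was tested as the interaction of CBD and LPS in GW mice. It was past the threshold for 3 genes in edgeR (adjusted p = 0.0386 each). Adamtsl4 (ENSMUSG00000015850, GRCm38 chromosome 3, 95676201 to 95687917) had an interaction of -4.65 ± 0.74 on the log2 scale (SE). The small GTPase gene Arl5c had 1.96 ± 0.32 and Slamf8, a SLAM family receptor gene of myeloid cells, 1.61 ± 0.27. Of 36 cell cycle genes all had a positive interaction, 14 past the list-alone threshold, with Stmn1 at 2.31 ± 0.51. Disease-associated genes were positive in 23 of 26 cases, Trem2 at 1.07 ± 0.28 and Cd9 at 1.23 ± 0.36 among them, and MHC genes in 22 of 23, as for H2-K1 (1.03 ± 0.32). P2ry12 had 1.09 ± 0.29 and did not pass (adjusted p = 0.118). Pacsin1 (2.68 ± 0.49) and Tha1 (-1.08 ± 0.19) had an adjusted p of 0.0561. Stmn1, Cd9 and H2-K1 were chosen after their values were seen.

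Each of the 3 calls was lost in 10 of the 14 fits that left out 1 library, and the interaction kept 0 calls without either GW-LPS replicate 3 or 4, any GW-CBD-PBS library, GW-PBS replicate 1 or 3, or GW-CBD-LPS replicate 1, 3 or 4. It held 211 without GW-CBD-LPS replicate 2, 92 without GW-LPS replicate 2 and 19 without GW-PBS replicate 2. When only the 4 groups were fitted edgeR called 0 (2328 at an unadjusted p under 0.05), while DESeq2 called 378 and limma voom with quality weights 2287, and with all groups 2540 genes had an unadjusted p under 0.05. The voom weight of GW-CBD-LPS replicate 1 was 5.94, against 0.43 to 0.69 in the rest of its group. With an estimated correlation the adjusted p values of the cell cycle, disease-associated and MHC lists were 0.692, 0.738 and 0.56.

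A score of the LPS response, built from the 1387 genes called higher and 1313 called lower in the 8 control libraries alone, gave 1 value per library. It averaged 0.54 ± 0.09 (SD, n = 4) in GW-PBS and 1.87 ± 0.11 (n = 3) in GW-LPS, 0.34 ± 0.06 (n = 3) in GW-CBD-PBS and 0.94 ± 0.33 (n = 4) in GW-CBD-LPS. GW-CBD-LPS replicate 3 was at 0.501, against 0.867 to 1.224 in the rest of its group and 0.303 to 0.407 in GW-CBD-PBS. LPS and PBS libraries differed by 1.34 without CBD (exact permutation p = 0.0286, the smallest that 3 against 4 libraries allow) and by 0.60 with CBD (exact permutation p = 0.0571), or 45% of that difference. The difference of -0.73 did not pass (exact permutation p = 0.0906, two-sided, all relabellings). Over the fixed interferon and cytokine lists the same difference was 0.34 (exact p = 0.274), of opposite sign.

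**Figure D4:**
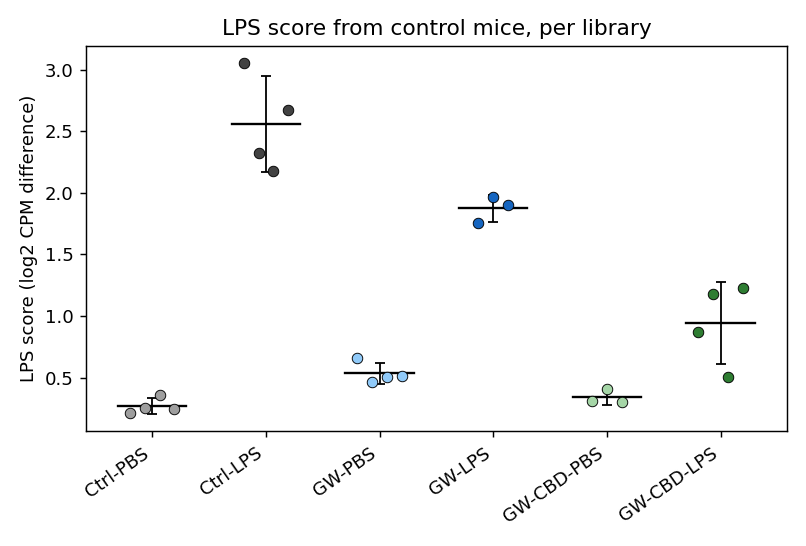
Mean log2 CPM of genes called higher minus that of genes called lower for LPS in control mice (vertical axis) in each library (points), with group mean (line) and SD (bars) of 6 groups. GW-LPS libraries lay between 1.75 and 1.97 and GW-CBD-LPS libraries between 0.50 and 1.22, and the control libraries, which defined the score, are shown for scale.

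Reversal of the exposure effect by CBD was examined as the correlation across genes of the GW and CBD contrasts, which share the GW libraries with opposite sign. Without LPS the correlation was -0.366, where simulated unchanged groups gave -0.468 (-0.506 to -0.435) and a covariance of -0.108 against the observed -0.088. With the 4 GW-PBS libraries split between both contrasts the mean correlation was 0.075 (-0.077 to 0.179). With LPS it was -0.135 against a simulated -0.569 (-0.591 to -0.549), with covariances of -0.046 and -0.143. The observed covariance minus the simulated one was 0.02 without and 0.096 with LPS. Over all genes neither correlation was more negative than the simulated range, and genes are not independent replicates. Over the 8651 genes of at least 3 log2 CPM the correlation without LPS was -0.599 and so below its simulated range (-0.491 to -0.433, simulated after that value was seen), but with the GW-PBS libraries split it averaged -0.107 (-0.51 to 0.442). A reversal among these genes was therefore not separated from the shared libraries. The simulation also gave each gene the same spread in every group. The real median SD was 0.401 in GW-PBS, 0.275 in Ctrl-PBS and 0.212 in GW-CBD-PBS, and after LPS 0.294 in GW-LPS, 0.364 in Ctrl-LPS and 0.356 in GW-CBD-LPS. As the spread of the shared libraries sets the correlation of unchanged groups, the simulated ranges decide in neither direction. Disease-associated genes such as Cst7 and Fabp5 were higher in GW-PBS than in both other PBS groups, but both differences rest on the same 4 GW-PBS libraries.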

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

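The tests of neutrophil markers, of the interferon list and of the LPS response in CBD-treated mice without the 3 libraries or by score were chosen after the result was seen, whereas the splits of the libraries and the tests of library size and spread were not.

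Neutrophil markers, most of them granule protein genes, summed to 25900 CPM in Ctrl-PBS replicate 3 against 541 to 684 CPM in the other 3 libraries of its group, and to 2650 CPM in Ctrl-LPS replicate 1 against 480 to 617 CPM. Of the 12 markers 11 had their highest value of all 22 libraries in Ctrl-PBS replicate 3, with Ngp at 9020, S100a9 at 5410 and Ltf at 4040 CPM, and Csf3r, which microglia also express, was the exception. Other brain cells in place of microglia would raise their markers. Those of astrocytes, oligodendrocytes and endothelial cells were 0.93, 0.91 and 0.83 of the other Ctrl-PBS libraries, which argues against these cells. The homeostatic microglia sum was 59690 CPM in Ctrl-PBS replicate 3 against 69850 to 75980 CPM in the other 3 libraries. A lower share of microglia through neutrophil RNA would not raise the markers of other brain cells, so these ratios do not address it. RNA of neutrophils or their precursors in single libraries is a candidate source, although the CD45mid and CD11a- gate should remove these cells. No biological explanation was tested, and a difference of 1 animal stays open.

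After LPS 69 genes passed in CBD-treated GW mice and 1577 in GW mice without CBD. With all libraries thinned to the smallest total 67 and 1600 passed, the median SD within the CBD groups was 0.82 of that in the GW groups, and without the 3 libraries 155 and 1120 passed, so library size, a larger spread over both CBD groups and those 3 libraries are argued against as the whole cause. A larger spread after LPS alone (median SD 0.356 in GW-CBD-LPS, 0.294 in GW-LPS, against 0.212 and 0.401 after PBS) and unequal quality of single libraries stay open, as voom with quality weights called 3779 and 3809 and edgeR called 260 in CBD-treated mice without GW-CBD-LPS replicate 3. A smaller response to LPS under CBD may be the reason and stays open, as the score difference of -0.73 had an exact permutation p of 0.0906. GW-CBD-LPS replicate 3 lay near the GW-CBD-PBS libraries. Its P2ry12 was at 5077.07 CPM (4907.39 to 5593.79 there, 2454.14 to 3517.43 in the rest of its group). Its C5ar1 was at 361.94 CPM (313.87 to 381.14, and 378.27 to 606.68) and its LPS score 0.501 (0.303 to 0.407, and 0.867 to 1.224). Whether this library responded less for a reason other than CBD was not tested. For the 607 calls in GW mice fitted alone, 1 of 35 splits of the 7 libraries was as large (highest other 1), which argues against chance. In genes at an unadjusted p under 0.05 another split gave more than the real groups (3737 against 3089), so chance is not excluded. Nor is it for the 59 calls in CBD-treated mice (2 of 35, highest other 457, with GW-CBD-LPS replicate 3 put among the PBS libraries).

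The interferon list was lower in GW-LPS than in Ctrl-LPS, by mean log2 CPM at -0.92, and at -0.71 without Ctrl-LPS replicate 1 (pooled SD 0.29), which argues against that library as the whole cause. Its median log2 fold change was -0.944, and -0.877 with the ribosomal protein covariate, which argues against variation that goes with those transcripts as the whole cause. A smaller interferon and cytokine response in GW mice stays open, because the difference of -1.05 over the fixed lists (exact permutation p = 0.0229) was taken in the libraries and genes in which the pattern had been seen and so restates it. Beside it stand the estimated correlation (adjusted p = 0.56) and the splits, where chance is not excluded (4 of 35 with at least 1857 genes at an unadjusted p under 0.05, highest other 2928). Library batches are not named in the labels and were not tested.

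For LPS in control mice 1 of 35 splits, the real one, gave as many calls (2700, highest other 0), which argues against chance as far as 35 splits can. Chance stays open for the other comparisons, given here with the number of splits as large, the real value and the highest other, in genes at an unadjusted p under 0.05 unless calls are named. These were exposure without LPS (23 of 35, 361, 3532), CBD with LPS (2 of 35, 2047, 2556), exposure by LPS (10 of 100 drawn, 1698, 4100) and CBD by LPS (9 of 100 drawn, 2328, 4477). For CBD without LPS it was 3 of 35 in calls (1, 723), and the split with 723 calls, GW-PBS replicates 1, 3 and 4 against the rest, points to a structure of the libraries, as do a split with 1653 calls for CBD by LPS, the one with 457 calls for LPS with CBD, and, for LPS in GW mice, GW-PBS replicate 2 with GW-LPS replicates 3 and 4 against the rest, with 3737 genes at an unadjusted p under 0.05 where the real groups gave 3089.

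Of 124 sets of a group's libraries 12 had a library far from the rest, where chance gives about 1 in 20, or 6.2. Monocyte markers were at 2360 CPM in Ctrl-PBS replicate 3 against 89.5 to 127 and at 821 CPM in Ctrl-LPS replicate 1 against 117 to 165. The glycolysis and hypoxia list was at 6030 CPM in Ctrl-PBS replicate 3 against 4400 to 4620. The antioxidant list was at 11200 CPM in GW-CBD-LPS replicate 4 against 7830 to 8210, and the astrocyte markers of that library were at 195 CPM against 226 to 230. Immediate early and heat shock genes summed to 14500 CPM in GW-PBS replicate 2 against 12200 to 12600. The endocannabinoid list was at 2840 CPM in GW-PBS replicate 1 against 3060 to 3100. Choroid and ependymal markers summed to 752 CPM in GW-PBS replicate 4 against 65.9 to 132. B cell markers summed to 581 CPM in Ctrl-LPS replicate 3 against 304 to 335. The LPS score of the exposure interaction was -6.15 in Ctrl-PBS replicate 3 against -0.853 to -0.172.

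The interaction of CBD and LPS passed for Slamf8 (1.61), Arl5c (1.96) and Adamtsl4 (-4.65), each with an edgeR adjusted p of 0.0386. Each call was lost in 10 of the 14 fits that left out 1 library, and 0 genes passed when only the 4 groups were fitted. In that fit 9 of 100 drawn splits, the real one included, gave as many genes at an unadjusted p under 0.05. Chance therefore stays open for these genes.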

How the results depend on the processing

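The fits without the 3 libraries with raised neutrophil markers and with a neutrophil or ribosomal protein covariate were chosen after seeing the data. In every setting called genes shared with edgeR kept their direction, but the ribosomal covariate kept 1914 of the 3378 calls for LPS in control mice (of 3768) and the fit of the compared groups 26 of the 69 for LPS with CBD (of 59). RLE size factors moved no count of calls by over 1.5 times, and exposure without LPS stayed at 0 in every setting. Without the low count filter 5 genes passed for exposure with LPS and 19 for CBD by LPS. DESeq2 called 342 (LPS with CBD), 135 (exposure with LPS), 883 (CBD with LPS), 57 (exposure by LPS) and 378 (CBD by LPS). Voom with quality weights called 3809 (LPS in GW mice), 3779 (LPS with CBD; 2071 higher, 1708 lower, against 65 and 4), 324 (exposure with LPS), 217 (CBD without LPS), 3512 (CBD with LPS), 111 and 2287 (the interactions). Its weights ran from 0.29 (GW-PBS replicate 1) to 5.94 (GW-CBD-LPS replicate 1), so its counts lean on the libraries of high weight. With only the compared groups 607 passed for LPS in GW mice, 1 for CBD without LPS (Tada2b), 0 for CBD with LPS and 0 for CBD by LPS (in edgeR; 2047 and 2328 at an unadjusted p under 0.05). Without the 3 libraries 155 passed for LPS with CBD, 672 for CBD with LPS and 5 for CBD by LPS. With the neutrophil covariate these were 120 (LPS with CBD) and 23 (CBD by LPS), with the ribosomal covariate 3759 (LPS in GW mice), 3 (LPS with CBD), 1253 (CBD with LPS) and 15 (CBD by LPS). The cause was not tested for any of these, nor below.

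Deviations of same-numbered libraries had a median correlation of 0.014 (-0.285 to 0.315, 11 of 51 pairs over 0.1), or -0.01 by title numbers. For differently numbered libraries the median was 0.002, or 0.012 by title numbers. No general pairing by number was seen, but a litter, day or batch shared by some libraries is not excluded. With the replicate block 0 genes passed for LPS with CBD and 0 for CBD by LPS, by title numbers 7 for LPS with CBD and 1 (Rtp4) for exposure with LPS, and the other counts moved by less than 1.5 times.

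Leaving out 1 library, counts ran from 2384 to 3417 (LPS in control mice), 733 to 2286 (LPS in GW mice), 0 to 260 (LPS with CBD), 0 to 75 (exposure with LPS), 97 to 532 (CBD with LPS), 0 to 13 (exposure by LPS) and 0 to 211 (CBD by LPS), and stayed at 0 for exposure without LPS and CBD without LPS. The score of exposure by LPS ran from -2.904 to 0.533 (18 of 22 omissions gave a value; exact p 0.296 to 0.982). Over the fixed lists it was -1.05 (exact permutation p = 0.0229), which restates the interferon pattern already seen. The score of CBD by LPS ran from -1.122 to -0.521 (exact p 0.0522 to 0.22) and was 0.339 over the fixed lists (exact p = 0.274). The correlation of exposure and CBD ran from -0.53 to -0.255 without LPS and from -0.347 to -0.052 with it, was -0.599 and -0.011 over genes of at least 3 log2 CPM, and -0.183 with LPS without the 3 libraries. With an estimated correlation 0 of 93 list calls held.

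The 204 named gene values gave 3680 values over all settings, of which 3187 kept direction and side of the threshold, 333 lost and 139 gained a call, and 21 changed sign. Elane for LPS in control mice was 3.22 without the 3 libraries and from -11.757 to 5.45 (without Ctrl-PBS replicate 3) leaving out 1 library, and Klf9 in GW mice from -0.127 (without GW-LPS replicate 3) to 3.518. The others lay near 0 in LPS with CBD and were not called: Ighm 0 (RLE), 0 (DESeq2), 0.033 (voom), 0.022 (block) and 0.005 (title block), Klf9 -0.316 (voom), Ddit4 -0.233 (voom), -0.184 (title block) and -0.074 (ribosomal covariate), and, leaving out 1 library, Ighm -0.066 to 0.062, Klf9 -0.183 to 0.31, Ddit4 -0.196 to 0.374 and Fkbp5 -0.03 to 0.252. Over all genes pooled, counting error is small beside the spread between libraries (chi-square of 11.7 to 234 per degree of freedom). This pooled value does not show how far depth limits genes with few counts.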

Other observations

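Among the tests here, those of glucocorticoid genes were written before their result was seen, and the genes of the next paragraphs were chosen after their values were seen.

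Several target genes of the glucocorticoid receptor rose with LPS in mice without CBD, while Cdkn1c fell in control (-1.16 ± 0.23) and GW mice (-1.62 ± 0.26) and Sgk1 fell in GW mice (-0.91 ± 0.18). In GW mice Ddit4 (adjusted p = 0.0563), Tsc22d3 (0.0574), Per1 (0.133), Mt1 (0.412) and Sult1a1 (0.0944) did not pass in edgeR. Fkbp5, a chaperone of that receptor, rose from 64.7 ± 4.79 to 388 ± 153 CPM (SD, n = 4 each) in control mice, a log2 fold change of 2.58 ± 0.41 (SE, edgeR adjusted p = 0.000143). In GW mice it rose from 93.3 ± 43.8 (n = 4) to 415 ± 327 CPM (n = 3; 2.15 ± 0.42). With CBD it was at 80.1 ± 6.91 (n = 3) and 87.3 ± 20.3 CPM (n = 4; 0.12 ± 0.42). Klf9, a transcription factor gene, rose by 2.93 ± 0.80 in control and by 2.99 ± 0.83 in GW mice, the latter call lost without GW-PBS replicate 1, 3 or 4 and its value -0.13 without GW-LPS replicate 3. Ddit4, an inhibitor of mTORC1 signalling, rose by 4.05 ± 0.69 in control mice and was lower with CBD after LPS (-3.35 ± 0.69, adjusted p = 0.0108, lost without GW-LPS replicate 3 or GW-CBD-LPS replicate 1), as was Fkbp5 (-2.25 ± 0.42, adjusted p = 0.00599, lost without GW-LPS replicate 3). The interaction of CBD and LPS did not pass for Fkbp5 (-2.03 ± 0.59, adjusted p = 0.149).

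A glucocorticoid signal to microglia after LPS, smaller under CBD, may be behind these genes, and 9 target genes whose values had not been seen when the test was written, Klf9 and Ddit4 among them, were used to test it. Of these 9, Errfi1 (-0.46), Cdkn1c (-1.16), Arrdc2 (-0.08) and Pdk4 (-0.01) were not higher after LPS in control mice, so their mean rests on the others. The mean log2 CPM of all 9 was higher in Ctrl-LPS than in Ctrl-PBS by 1.23 (exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow), as such a signal needs. After LPS the difference between GW mice with and without CBD was -0.96 (exact permutation p = 0.0857), so that part stays open. The mean was 3.59 ± 1.12 (SD, n = 3) in GW-LPS, whose libraries were spread widely, and 2.62 ± 0.15 (n = 4) in GW-CBD-LPS. These 9 genes were read in the libraries that had prompted the idea, and no set of unrelated genes was compared with them. Their rise in control mice is therefore not shown to be particular to a glucocorticoid signal. Hormone levels were not measured in the data used here.

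Of 5 clock output genes, whose transcription follows the circadian oscillator, Nr1d1 (adjusted p = 0.0639) and Nr1d2 (0.183) did not pass for LPS in GW mice in edgeR, and the list was not tested as a group. Dbp fell from 9.42 to 2.02 CPM in control mice (-2.22 ± 0.51) and from 14 to 3.24 CPM in GW mice (-2.11 ± 0.55, lost without GW-LPS replicate 2 or 4), and was at 10.5 ± 2.07 (n = 3) and 20.3 ± 18.9 CPM (n = 4) with CBD (0.96 ± 0.52, adjusted p = 0.521). Hlf fell by 3.74 ± 0.51 and by 2.81 ± 0.54 and had -0.64 ± 0.48 with CBD. The interaction of CBD and LPS did not pass for Dbp (3.07 ± 0.76, adjusted p = 0.0913) or for Nr1d1, a nuclear receptor gene of the clock (2.72 ± 0.65, adjusted p = 0.0834). The hour of brain collection is not in the labels.

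B cell marker transcripts were lower after LPS in mice without CBD, and which of the sorted cells held them was not tested. B cell markers summed to 1130 CPM in Ctrl-PBS and 382 CPM in Ctrl-LPS, to 1000 and 499 CPM in GW mice, and to 1110 and 1050 CPM with CBD. Ighm alone was at 963 CPM in Ctrl-PBS, 334 CPM in Ctrl-LPS and 950 CPM in GW-CBD-LPS, so these sums mostly restate that gene. Ighm, the immunoglobulin M heavy chain gene, fell by 1.53 ± 0.28 in control and by 1.09 ± 0.31 in GW mice, lost without GW-PBS replicate 1 or 3 or GW-LPS replicate 3 or 4, and stayed at 951 and 950 CPM with CBD. After LPS Ighd was higher with CBD (1.64 ± 0.31, adjusted p = 0.00645), as was Cd79b (0.92 ± 0.21, adjusted p = 0.0234, lost in 5 of 7 fits that left out 1 library), and Ighm did not pass (1.13 ± 0.31, adjusted p = 0.0589). The interaction of CBD and LPS did not pass for Ighm either (1.09 ± 0.43, adjusted p = 0.251). The B cell list had an adjusted p of 0.738 with an estimated correlation for CBD with LPS.

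Other lists were mixed after LPS in control mice. Of 27 tolerance and checkpoint regulators 6 rose and 5 fell, and of 21 senescence genes 6 rose and 2 fell, with the cell cycle inhibitor gene Cdkn1a at 0.92 ± 0.24. Of 27 immediate early and heat shock genes 7 rose and 1 fell (adjusted p = 0.809 with an estimated correlation), of 19 lipid efflux and storage genes 4 rose and 3 fell, and of 21 cholesterol synthesis genes 2 rose. Of 10 genes encoded by the mitochondrial genome 1 rose. Among markers of other cells 3 of 8 mural cell genes and 3 of 11 endothelial genes fell and 2 endothelial genes rose, of 11 markers of border-associated macrophages 3 rose and 2 fell, and no neuron, astrocyte or oligodendrocyte precursor marker passed in edgeR.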
